A study of Homo sapiens with 18 samples.

How the data were processed

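The deposited table held 14447 genes in 18 columns, 1 per library, and every column matched a sample. Per the submitters' processing notes, the tools were FastQC 0.11.5, TopHat2 2.0.14, SAMtools 1.2, HTSeq and DESeq2, with the hg38/GRCh38 human genome. The notes gave no role or order for these tools, and stated neither the annotation release nor the strand setting. Per the submitters' extraction notes, RNA came from the RNeasy Plus Micro kit and was checked on a BioAnalyzer. The authors deposited variance-stabilized values on a log2-like scale, with a common floor of 3.711 for 0 reads and a highest value of 19.6. Near the floor a difference of 1 unit stands for a change in reads that depends on the transformation. Far above the floor, 1 unit is close to a doubling.

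Gene identifiers were matched to GENCODE release 29 on GRCh38, by identifier without its version. Of the 14447 identifiers, 14419 matched, 12560 of them with the same version, and 28 did not. Among all genes, 99.5% were annotated as protein coding. Y-linked genes, XIST and TSIX (10 in all) were left out before any fit, because the donors are people, which left 14437 genes. Genes of T cell receptor segments were not used here, and the table held none of those in the lists.

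Inverting the transformation gave normalised read counts, and 100% of the values above the floor lay within 0.01 of a whole read after division by a step for each library. The largest distance from a whole read was 0.00206. The read totals given in the text are sums of these recovered reads over the genes of the table. Each gene of the table had at least 7 reads in total and a read in at least 2 libraries. Normalised counts are printed as group means with their SD over 6 libraries. Limits from a count of 0 use a floor of 3 counts over the group and cover counting error only, since the reads carry no molecular identifiers that the labels mention.

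Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited values, with all 3 groups in 1 linear model, a variance trend and empirical Bayes moderation. The tests were two-sided, and p was adjusted by Benjamini and Hochberg's method over the 12213 genes with at least 6 of 18 libraries more than 1 unit above the floor. A gene was called at an adjusted p under 0.05, and a call of at least 1 unit was counted as large. Each adult donor gave a CD4+ and a CD4− library, so the adult pair was also fitted with the donor as a fixed block over the 12 adult libraries, and all libraries with the donor as a random block (correlation 0.817). Differences are given in units of the deposited scale with their standard error. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.

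A simulated test of the same models changed 50 genes at each of 4 sizes among 12213 genes. For cord CD4+ against adult CD4+, 8% of the genes were recovered at 0.5 units, 44% at 1 unit, 92% at 2 units and 100% at 4 units, with 12 calls among 12013 unchanged genes. For adult CD4− against adult CD4+, the recovered shares were 6%, 34%, 92% and 100% at those sizes, with 0 calls among 12013 unchanged genes. With the donor as a fixed block they were 60%, 96%, 100% and 100%, with 15 calls among the unchanged genes. For the overlap of the 2 contrasts, unchanged groups with donor pairs were simulated 100 times from the spread of each gene, and as many genes as had been called were taken by the largest t in each direction. This simulation and the overlap in the splits of the donors were added after the data were seen.

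Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule always named CD4, CD8A, CD8B, NRP1 and IL10. It named the 10 largest rises and the 10 largest falls of cord CD4+ against adult CD4+ among called genes whose groups did not overlap. For adult CD4− against adult CD4+ it named as many among called genes with the same sign in all 6 donors, and for cord CD4+ against adult CD4− the 5 largest each way without overlap. From each list it named at most 4 called members with the smallest p in the 2 main comparisons, and list members given as not called. T cell receptor, immunoglobulin, HLA and KIR genes, clone names and non-coding names were left out of the largest changes. Other genes named in the text are list members or were chosen after their values were seen, which the text says at that place. Some genes that the rule names are not reported here, although they count in the totals of calls and lists.

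Of the 27 lists, 25 had tested members. The list of red cell and platelet markers had 1 gene in the table and 0 tested, and the list of γδ T cell markers had 0 in the table, so neither was analysed here. Lists were tested with camera against all other genes tested, with a preset correlation between genes of 0.01 and adjustment over the 25 lists within a comparison. Beside it, camera with an estimated correlation and fry were run. Members were also counted with p adjusted over the list alone. The titles of the libraries spell the subset in 2 ways, with lower-case or capital letters, and each group has 3 libraries of each spelling. Cord CD4+ replicate 6 has a capital title. The labels do not say whether the spelling marks a round of preparation, so counts were also computed within each spelling and with the spelling as a covariate.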

Results

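Bulk RNA sequencing measured gene expression in invariant natural killer T (iNKT) cells, T cells with a semi-invariant receptor for lipids presented by CD1d. Per the series description, the cells had been expanded, were at rest, and were sorted by CD3, the iNKT receptor and CD4. The 18 libraries form 3 groups of 6, which are adult peripheral blood CD4+, adult peripheral blood CD4− and cord blood CD4+ cells. The adult libraries are paired, with both subsets from each of 6 donors. Recovered read totals ranged from 16.6 to 25.4 M reads per library. They averaged 18.2 M ± 0.81 (SD, n = 6) in adult CD4+, 19.2 M ± 1.60 in adult CD4− and 21.1 M ± 2.56 in cord CD4+ libraries. Mitochondrial transcripts took 8.05% ± 3.11 of the reads in adult CD4+, 6.41% ± 3.66 in adult CD4− and 3.74% ± 0.973 in cord CD4+ libraries. On genes with group means removed, each adult CD4+ library was compared with the adult CD4− libraries. It correlated best with that of its own donor (r from 0.770 to 0.857 across genes, highest with another donor's CD4− library 0.594). Genes are not independent replicates.

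The first principal component held 34.1% of the variance. Cord CD4+ replicates 1 to 5 scored between 46.0 and 68.3 on it, while cord CD4+ replicate 6 scored −24.3, within the range of the adult libraries. All libraries were also thinned to equal reads and put on log2(normalized count + 1) values. There cord CD4+ replicate 6 scored 5.32, between the adult libraries (−61.7 to −13.4) and the other cord libraries (75.2 to 88.3). The scale changed along with the depth, so the shift from −24.3 cannot be credited to depth.

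**Figure D1:**
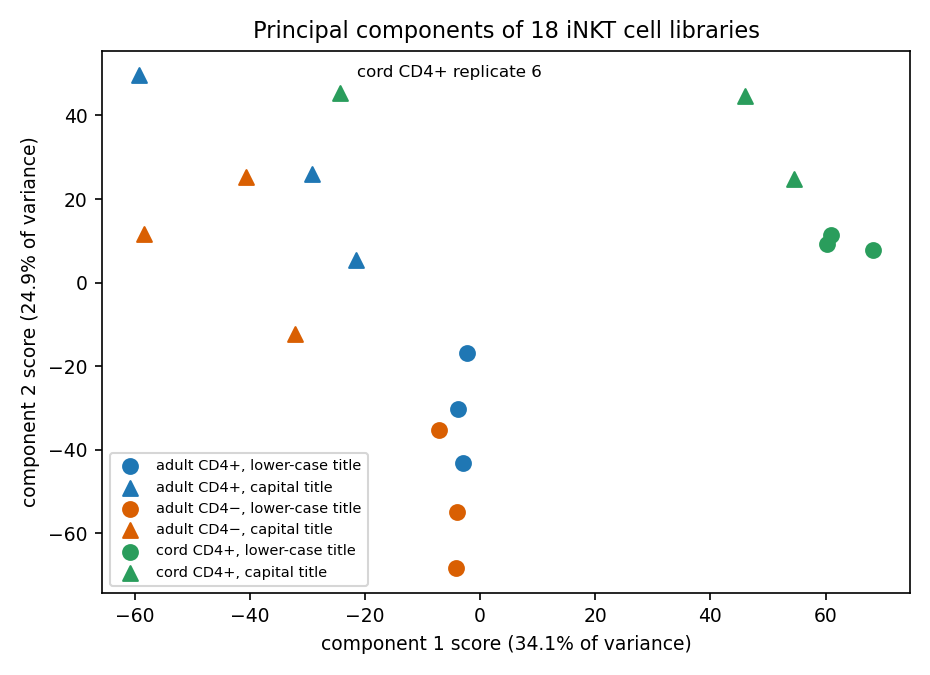
Scores of the 18 libraries on the first 2 principal components of the deposited values, in units of that log2-like scale, with a point per library, colours for the groups and shapes for the spelling of the title. Cord CD4+ replicates 1 to 5 lie between 46.0 and 68.3 on the first component and cord CD4+ replicate 6 lies at −24.3.

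Cord CD4+ against adult CD4+ cells asks how the source of the blood relates to expression within the CD4+ subset, and the series title names a regulatory, IL10-producing type (NKT10) and NRP1. Of 25 tested members of the list of NKT10 and regulatory T cell genes, 8 rose in cord cells, and the list did not keep its call with an estimated correlation (adjusted p = 0.217). IL10, a suppressive cytokine, had 207 ± 167 normalised counts (SD, n = 6) in cord and 0 reads in all 6 adult CD4+ libraries. NRP2 and PDCD1, a semaphorin and VEGF co-receptor and the inhibitory receptor PD-1, rose from 181 to 2606 and from 134 to 1164 counts. NKG7 (a granule protein), IFNG (interferon-γ), HLA-DRA (antigen presentation) and INSIG1 (a regulator of cholesterol synthesis) fell in cord cells, although none of their lists kept its call with an estimated correlation (adjusted p = 0.217 each). GZMK, a granzyme, fell from 3031 ± 1935 to 89.1 ± 93.7 counts (52.9 without cord CD4+ replicate 6, which had 270).

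In all, 657 genes were higher and 655 lower in cord CD4+ than in adult CD4+ cells, of which 379 and 378 differed by at least 1 unit. That fit took the paired adult libraries as independent. With the donor as a random block 561 were higher and 569 lower (1072 of the 1312 calls shared). With the 2 groups alone the counts were 518 and 531. The 10 largest rises and falls were taken from called genes whose groups did not overlap, so their separation was set by that choice. Among the rises, PLS3, an actin-bundling protein, rose by 4.93 ± 0.46 units (4.31 to 695 counts, with an adult mean of 1.03 without adult CD4+ replicate 4), and CSF2RB, the shared receptor chain for IL-3, IL-5 and GM-CSF, rose by 4.05 ± 0.45 (435 to 8765 counts). The others were ADGRL2 (an adhesion receptor), KIAA1217, HIC1 (a transcriptional repressor), NPTX1 (a pentraxin), CD93 (a C-type lectin), LGMN (a lysosomal protease), FN1 (fibronectin) and P2RY1 (an ADP receptor). With HLA genes left out by the rule, the largest falls were GZMK at −4.77 ± 0.55 units, TYROBP (an adaptor of NK receptors) at −4.64 ± 0.58 and PLEK (pleckstrin) at −4.46. SLC4A10 (a bicarbonate transporter), LY9 (a SLAM family receptor), FGFBP2 (secreted by cytotoxic lymphocytes), NEO1 (neogenin), TMEM98, PPP2R2B (a phosphatase subunit) and BEX5 followed.

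IL10 lies on chromosome 1 at 206767602 to 206772494 (GRCh38, ENSG00000136634.5) and its cord libraries held 12 to 488 reads. Over the group, cord cells had 12.0 CPM (counts scaled to the read total). The 0 reads in adult CD4+ cells allow up to 0.0274 CPM. The level pooled over the cord libraries was thus at least 437-fold higher. This bound covers counting error, leaves out the spread between donors, and does not hold for each cord library. The limma test called IL10 (adjusted p = 1.8e-05, 6 of 6 cord libraries above every adult CD4+ one), and its fitted difference depends on the transformation. NRP1, a semaphorin and VEGF co-receptor on chromosome 10 at 33177492 to 33336262 (ENSG00000099250.17), rose from 8.33 ± 6.69 to 89.4 ± 78.4 counts. Its difference was 1.71 ± 0.48 units (adjusted p = 0.0267), with 5 of 6 cord libraries above the highest adult CD4+ library. It was 1.99 units (adjusted p = 0.00183) within lower-case titles and 1.43 units (adjusted p = 0.549) within capital titles. Of the cord libraries with capital titles, replicates 4 and 5 had 182 and 190 NRP1 counts and replicate 6 had 1.16. The weaker result there therefore cannot be credited to the spelling. The NRP1 call was lost without adult CD4+ replicate 1 (adjusted p = 0.0510) or 3 (0.0680) and without cord CD4+ replicate 1 (0.0548), 4 (0.0680) or 5 (0.0678), while without cord CD4+ replicate 6 the difference was 2.16 units (adjusted p = 6.4e-04). IL10 differed by 3.88 units (adjusted p = 4.6e-04) and 3.52 units (adjusted p = 0.0558) in those sets. CD4, the sort gene, had 12531 and 20637 counts in adult and cord cells (0.71 units, adjusted p = 0.275). CD8A and CD8B, the chains of CD8, differed by −0.71 (adjusted p = 0.467) and 0.60 units (adjusted p = 0.623). Cord CD4+ replicate 6 had the highest cord counts of both (1832 and 783). Without it the cord mean of CD8A was 291, against 548.

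**Figure D2:**
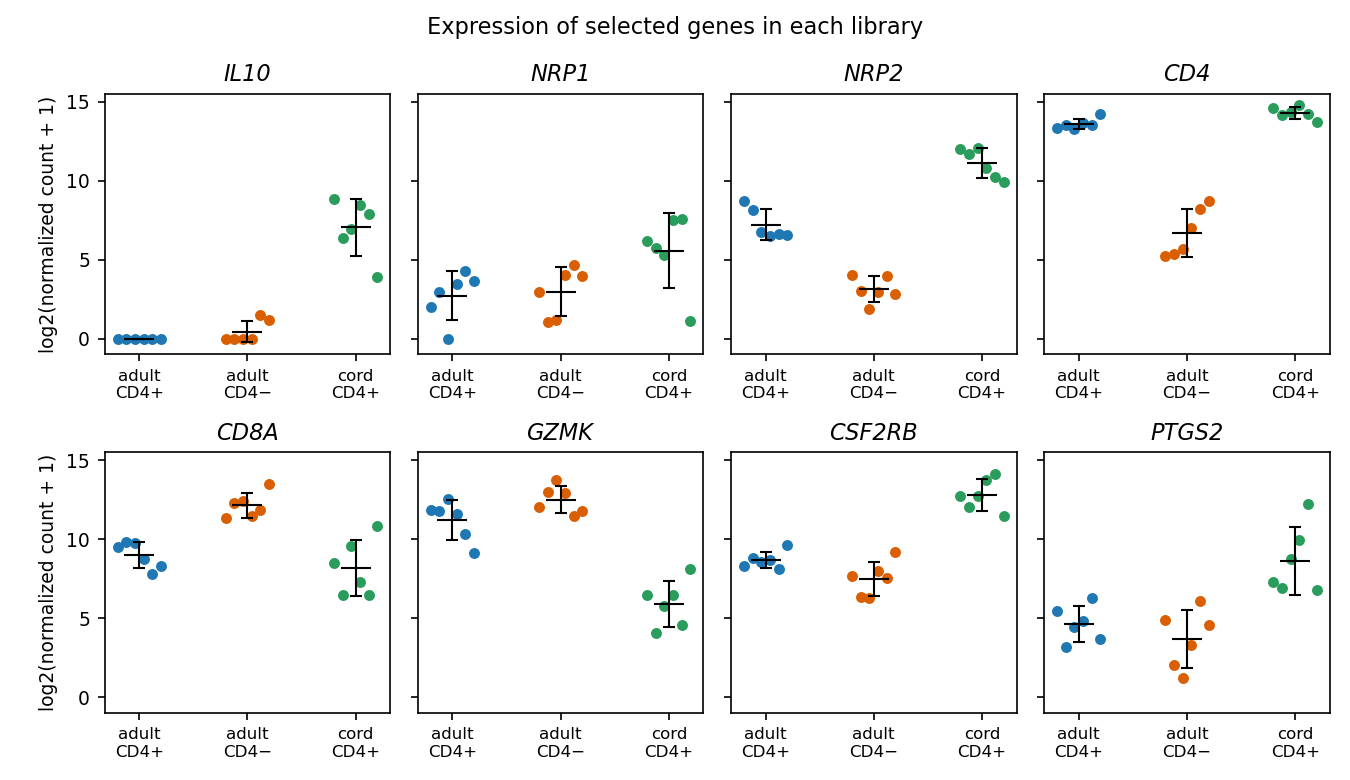
Expression of 8 genes as log2(normalized count + 1), with a point per library and lines for the mean and SD of each group of 6. IL10 had 0 reads in all 6 adult CD4+ libraries and 207 counts on average in cord CD4+ libraries.

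In that list of NKT10 and regulatory genes, 8 of 25 rose and 0 fell, also when adjusted over the list alone. The members that rose were IL10, NRP1, PDCD1, AHR (a ligand-activated transcription factor, 1.63 units), LRRC32 (which holds latent TGF-β, 2.36), NT5E (the ectonucleotidase CD73, 2.25), FOXP3 (the regulatory T cell factor, 1.63) and IKZF4 (an Ikaros family factor, 1.15). The list tested higher than other genes (camera adjusted p = 6.5e-04), but not with an estimated correlation (adjusted p = 0.217). The series title names the subject of this list, so it is not independent evidence of its direction. Of 15 neuropilin ligands and co-receptors, 5 rose and 2 fell (5 and 3 adjusted over the list alone). NRP2 rose by 3.68 ± 0.40 units, PLXNA4 (a plexin) by 2.79 and PLXNA1 by 1.66, and SEMA4A (a semaphorin) fell by 3.00 ± 0.38. That list did not test apart from other genes (adjusted p = 0.0942).

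Among 15 cytotoxic effectors, 7 fell and 0 rose (8 fell adjusted over the list alone). GZMK, NKG7 (a granule protein, −3.05 units) and GZMM (a granzyme, −2.08) were among them. The list was lower (camera adjusted p = 4.3e-05; adjusted p = 0.217 with an estimated correlation). Of 18 NK receptors and adaptors, 5 fell and 2 rose (7 and 3 adjusted over the list alone). NCR3 (an activating receptor) changed by −2.96 ± 0.27 units and KLRD1 (CD94) by −3.13 ± 0.51, while FCER1G (an Fc receptor chain) rose by 2.77 and SH2D1B (a SLAM adaptor) by 1.54. This list tested lower (camera adjusted p = 0.0101; adjusted p = 0.319 with an estimated correlation). Of 17 Th1 genes, 8 fell and 1 rose, with the same counts adjusted over the list alone. IFNG (interferon-γ) changed by −2.74 units, CCL5 (a chemokine) by −3.24 and EOMES (a T-box factor) by −2.92, and IL18R1 (an IL-18 receptor chain) rose by 1.52. The Th1 list was lower (camera adjusted p = 2.0e-04; adjusted p = 0.217 with an estimated correlation). CCL3 and CCL4 have close paralogs, whose reads can be shared.

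Of 10 MHC class II genes, 6 fell (9 adjusted over the list alone), among them HLA-DRA (11121 to 1567 counts) and HLA-DPA1 (4949 to 590 counts). The list was lower (camera adjusted p = 8.5e-07; adjusted p = 0.217 with an estimated correlation), and reads of these variable genes can be lost or shared between paralogs. Of 18 cholesterol synthesis genes, 9 fell (12 adjusted over the list alone). INSIG1 (a sterol sensor partner) changed by −1.96 ± 0.30 units and FDFT1 (squalene synthase) by −1.43. The list was lower (camera adjusted p = 8.3e-10; adjusted p = 0.217 with an estimated correlation). Of 18 immediate early genes, 5 fell (6 adjusted over the list alone), with FOS at −2.10 and CD69 (an activation marker) at −1.91 units. That list was also lower (camera adjusted p = 0.00203; adjusted p = 0.319 with an estimated correlation). Of 19 glycolysis genes, 2 rose (6 adjusted over the list alone), which were SLC16A3 (a lactate exporter, 1.96 units) and HK2 (hexokinase, 1.56), against 7 without cord CD4+ replicate 6. This list was higher (camera adjusted p = 0.00106; adjusted p = 0.402 with an estimated correlation).

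Of 5 tested fetal and progenitor genes, 3 rose (3 higher and 1 lower adjusted over the list alone). They were IGF2BP3, a fetal RNA-binding protein (23.1 to 340 counts), SOX4 (36.7 to 143 counts) and ARID3A (339 to 673 counts). The list was higher (camera adjusted p = 0.0146; adjusted p = 0.319 with an estimated correlation). Of 15 listed monocyte and dendritic cell markers, 10 were in the table and 4 passed the low-value filter. Of these 4, 3 rose, which were LYZ (lysozyme, 59.7 to 731 counts), CST3 (cystatin C, 26.2 to 220) and VCAN (versican, 0.992 to 91.8). VCAN had at most 3.94 counts in adult libraries and passed the filter only through the cord libraries. The list was higher (camera adjusted p = 0.0101; adjusted p = 0.217 with an estimated correlation). These markers and the mitochondrial share differed between the same groups of libraries as the genes above, and their relation across libraries was not tested. Of 13 mitochondrially encoded transcripts, 4 fell (10 adjusted over the list alone; camera adjusted p = 1.1e-05; adjusted p = 0.319 with an estimated correlation). Single libraries moved some of these means, and without adult CD4+ replicate 5 the adult mean was 10.6 counts for IGF2BP3 and 24.01 for SOX4. The cord mean of LYZ was 387 without cord CD4+ replicate 4 and that of VCAN 56.2 without cord CD4+ replicate 2, and the adult mean of VCAN was 0.402 without adult CD4+ replicate 4. The LYZ call (2.37 units, adjusted p = 0.0400) was lost without adult CD4+ replicate 1 (adjusted p = 0.0772), 3 (0.0921) or 5 (0.0733) and without cord CD4+ replicate 1 (0.0881), 4 (0.0917) or 5 (0.0502). It was also lost on log2 counts (0.0560), with quality weights (0.381), the 2 groups alone (0.0831), a random donor block (0.101) and limma-voom (0.0960), and within lower-case (0.216) and capital titles (0.0923). Of 5 B cell markers, 1 rose (2 adjusted over the list alone; camera adjusted p = 0.176), namely BANK1 (4.60 to 105 counts).

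The other lists did not test apart from the remaining genes. Of 14 listed iNKT and T cell identity genes, 9 were in the table, and the T cell receptor genes of the list were not among them. Of the 9, 0 were called by limma (1 at an unadjusted p under 0.05, 0 by limma-voom; camera adjusted p = 0.914). Of 26 cell cycle genes, 0 were called by limma (1 at an unadjusted p under 0.05, 0 by limma-voom; camera adjusted p = 0.167). Among 12 Th2 genes (camera adjusted p = 0.641), HPGDS (a prostaglandin D synthase, 3.07 units) and IL4R rose and IL4 fell by 3.20 units. The Th17 list had 1 fall of 7 members (IL23R, −2.32 units; camera adjusted p = 0.108). Of 14 naive and memory homing genes, 2 rose and 2 fell (camera adjusted p = 0.825). Of 12 inhibitory receptors, 2 rose and 1 fell (camera adjusted p = 0.222), with BTLA at −2.59 units. Of 20 chemokine receptors and integrins, 1 rose and 2 fell (camera adjusted p = 0.577). The 8 genes of the CD4 and CD8 lineage held 1 rise, TOX (2.64 units), and 1 fall, RUNX3 (camera adjusted p = 0.395). Of 12 heat shock genes 1 fell (camera adjusted p = 0.157), and of 18 interferon response genes 3 rose and 1 fell (camera adjusted p = 0.157). Of 15 cytokine receptors 3 rose and 1 fell (camera adjusted p = 0.649, with a median of −0.03 and a mean of 0.21 units). Of 6 MAIT cell markers, 1 rose and 1 fell (camera adjusted p = 0.641). Adjusted over the list alone, these lists had the same counts, except the Th2 list with 2 higher and 2 lower.

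**Figure D3:**
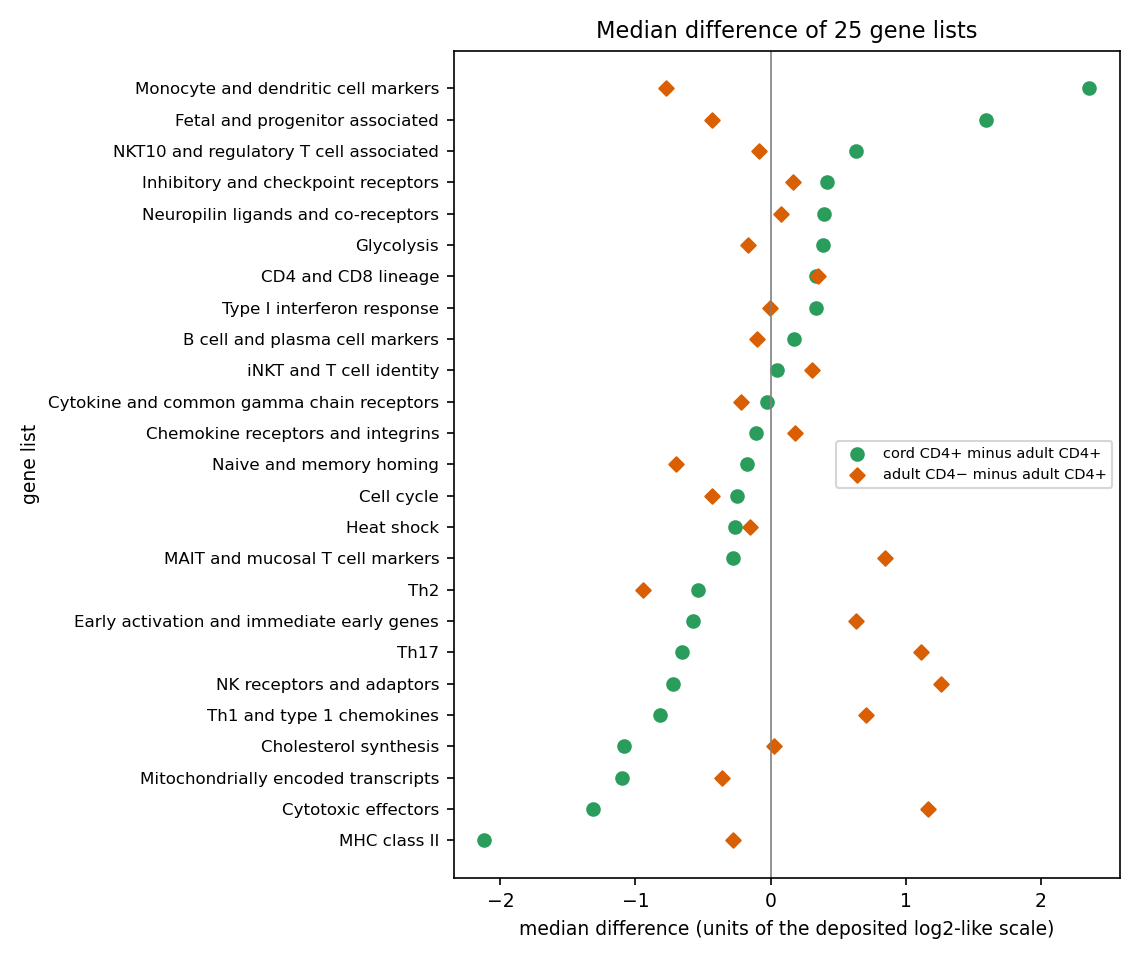
Median difference of the tested members of each gene list, in units of the deposited log2-like scale, for cord CD4+ minus adult CD4+ (circles) and adult CD4− minus adult CD4+ (diamonds), with the 25 lists ordered by the first. Cytotoxic effectors lie at −1.31 in the first and 1.17 in the second.

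Without cord CD4+ replicate 6 the counts were 1357 higher and 1449 lower, with 1301 of the 1312 calls shared. In lists, that left chemokine receptors and integrins with 3 higher (against 1), Th2 genes with 3 lower (against 1), cytokine receptors with 2 lower (against 1) and B cell markers with 2 higher (against 1). Immediate early and cell cycle genes had 1 higher and identity genes 1 lower, against 0. Some lists that were not called changed direction, as cell cycle genes did from a median of −0.25 to 0.00 units and identity genes from 0.05 to −0.04. Without cord CD4+ replicate 2 the lower genes were 418. Of 85 called genes that the rule names, 70 kept their call without each library in turn, and RUNX3, HK2, LYZ and NRP1 were among the 15 that did not. With the donor as a random block, 77 of the 85 kept their call and 8 did not. Within lower-case titles 1696 genes were higher and 1745 lower, and within capital titles 38 and 58. Cord CD4+ replicate 6 is among the cord libraries with capital titles. The lower counts there cannot be credited to the spelling apart from this library.

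Adult CD4− against adult CD4+ cells asks how the subsets of the same donors differ. The lists of NK receptors and cytotoxic effectors were higher in CD4− cells without the donor block, also with an estimated correlation. With the block they kept their call at the preset correlation, but with an estimated correlation neither was called (camera adjusted p = 0.0842 and 0.0559). CD8A, a chain of CD8, rose from 580 ± 298 to 5190 ± 3313 normalised counts (SD, n = 6). CD4 fell from 12531 ± 3241 to 161 ± 162 counts. KLRC1, the NK receptor NKG2A, rose from 159 to 1621 counts, and CYSLTR1, a leukotriene receptor, fell from 326 to 15.3 counts (8.29 without adult CD4− replicate 4, which had 50.1). IL10 and NRP1 were near the floor in both subsets.

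Without regard to donors, 25 genes were higher and 17 lower in CD4− cells, 24 and 16 of them by at least 1 unit. With the donor as a fixed block, 763 were higher and 583 lower, 152 and 117 by at least 1 unit, and all 42 genes called without the block were among them. CD4 differed by −6.51 ± 0.41 units (adjusted p = 2.4e-08; 1.5e-07 with the donor block), lower in 6 of 6 donors. CD8A differed by 3.08 ± 0.60 units (adjusted p = 0.0280; 7.0e-05 with the block), and CD8B by 2.89 ± 0.71 (adjusted p = 0.112; 5.0e-05 with the block), each higher in 6 of 6 donors. Without the block, the CD8A call was lost without adult CD4+ replicate 4 (adjusted p = 0.0507), 5 (0.0769) or 6 (0.0742) and without adult CD4− replicate 2 (0.0751), 3 (0.0771), 4 (0.0545) or 6 (0.0536). It was also lost within lower-case titles (2.26 units, adjusted p = 0.139) and capital titles (3.90 units, adjusted p = 0.851). The other large falls were NRP2 (181 to 8.83 counts), PTP4A3 (a phosphatase), CFP (properdin), CTSL (cathepsin L), RTKN2, ANKRD55, FBLN7 and GCSAM. The large rises were KLRC1 at 3.18 ± 0.49 units, PECAM1 (an adhesion molecule), KLRD1 (2.61), CD244 (a SLAM receptor, 2.37), IL17RE (an IL-17 receptor), DBN1 (an actin-binding protein), KLRK1 (NKG2D, 2.21), STYK1 and CRTAM. Reads of KLRK1 and KLRC1 can be shared with neighbouring paralogs and a read-through gene. NRP1 differed by 0.14 units (adjusted p = 0.999; 0.627 with the block) and IL10 by 0.16 units (adjusted p = 0.999; 0.525 with the block).

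Of 18 NK receptors and adaptors, 5 rose (11 adjusted over the list alone, 14 with the donor block), with camera adjusted p = 2.5e-23 and adjusted p = 0.00208 with an estimated correlation. Of 15 cytotoxic effectors, 1 rose, FASLG (Fas ligand, 496 to 1338 counts), against 5 adjusted over the list alone and 13 with the block. That list was higher (camera adjusted p = 2.8e-13; adjusted p = 0.0301 with an estimated correlation). PRF1 (perforin) had 7661 and 17510 counts and was called with the block (adjusted p = 1.5e-05). The Th1 list was higher with 0 of 17 members called by limma (7 at an unadjusted p under 0.05, 0 by limma-voom, 2 adjusted over the list alone, 10 with the block). Its camera adjusted p was 3.7e-07, and adjusted p = 0.0475 with an estimated correlation, but the list was not called by fry (adjusted p = 0.0606), which tests whether its members move one way on balance. The Th17 list was higher with 0 of 7 called (5 at an unadjusted p under 0.05, 0 by limma-voom, 5 adjusted over the list alone, 6 with the block), with camera adjusted p = 7.4e-08 and adjusted p = 0.0303 with an estimated correlation. The Th2 list was lower with 0 of 12 called (5 at an unadjusted p under 0.05, 0 by limma-voom, 0 adjusted over the list alone, 7 lower with the block). Its camera adjusted p was 4.8e-06, and adjusted p = 0.00946 with an estimated correlation. CCR4, a Th2 chemokine receptor, had 3599 and 1314 counts (adjusted p = 0.970; 1.7e-04 with the block). With the donor block, these 5 lists kept their call with the preset correlation, and adjusted p lay from 0.0504 to 0.117 with an estimated correlation.

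Lists whose call was lost with an estimated correlation had 0 members called by limma without the block and 0 by limma-voom. Adjusted over the list alone, chemokine receptors and integrins had 4 higher and 1 lower, MAIT cell markers 1 higher, naive and memory homing genes 1 lower and monocyte markers 1 lower. Immediate early genes were higher (camera adjusted p = 6.8e-07; adjusted p = 0.0805 with an estimated correlation), with 4 of 18 at an unadjusted p under 0.05 and 7 called with the block. MAIT cell markers were higher (camera adjusted p = 1.2e-05; adjusted p = 0.0805 with an estimated correlation), with 3 of 6 at an unadjusted p under 0.05 and 5 called with the block. Chemokine receptors and integrins were higher (camera adjusted p = 0.0151; adjusted p = 0.264 with an estimated correlation), with 8 of 20 at an unadjusted p under 0.05 and, with the block, 8 higher and 2 lower. Naive and memory homing genes were lower (camera adjusted p = 7.3e-04; adjusted p = 0.151 with an estimated correlation), with 5 of 14 at an unadjusted p under 0.05 and, with the block, 2 higher and 7 lower. Cell cycle genes were lower (camera adjusted p = 1.3e-05; adjusted p = 0.461 with an estimated correlation), with 0 of 26 at an unadjusted p under 0.05 and 7 called with the block. Glycolysis genes (camera adjusted p = 0.00716; adjusted p = 0.461 with an estimated correlation) and mitochondrial transcripts (camera adjusted p = 0.00418; adjusted p = 0.461 with an estimated correlation) were lower, with 2 and 0 members at an unadjusted p under 0.05. Monocyte markers were lower (camera adjusted p = 0.0284; adjusted p = 0.0805 with an estimated correlation), with CD33 at 240 and 44.2 counts (adjusted p = 0.0552; 1.8e-04 with the block). With the donor block that last list was not called (adjusted p = 0.153).

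The remaining lists did not test apart from other genes without the block. NKT10 and regulatory genes had 0 of 25 called by limma (4 at an unadjusted p under 0.05, 0 by limma-voom), and with the block 3 were higher and 7 lower (camera adjusted p = 0.0757; 0.171 with the block). Among these, TNFRSF4 (OX40) had 609 and 117 counts (adjusted p = 0.0561; 3.3e-05 with the block), and LAG3, an inhibitory receptor, had 1430 and 3986 (adjusted p = 0.762; 1.5e-05 with the block). The CD4− mean of TNFRSF4 was 69.6 without adult CD4− replicate 6, and the CD4+ mean of LAG3 was 900 without adult CD4+ replicate 6. Identity genes held 1 call, CD4 (camera adjusted p = 0.989, with a median of 0.31 and a mean of −0.51 units). The CD4 and CD8 lineage held 1 rise and 1 fall (camera adjusted p = 0.546), and the neuropilin list 1 fall, NRP2 (camera adjusted p = 0.953). Fetal genes (camera adjusted p = 0.125; 0.0111 with the block) and heat shock genes (camera adjusted p = 0.0757; 0.0286 with the block) were called lower with the block, but not with an estimated correlation (adjusted p = 0.117 and 0.429 with the block). The camera adjusted p was 0.430 for inhibitory receptors, 0.989 for interferon response genes, 0.484 for MHC class II, 0.989 for cholesterol synthesis, 0.121 for cytokine receptors and 0.270 for B cell markers. Their members called by limma without the block were 0, with 1, 0, 0, 0, 3 and 2 at an unadjusted p under 0.05 and 0 by limma-voom. Adjusted over the list alone, NKT10 and regulatory genes had 1 lower, the CD4 and CD8 lineage 2 higher and 1 lower, the neuropilin list 1 higher and 1 lower, identity genes 1 lower and cytokine receptors 1 lower. With the block, the members called higher and lower were 5 and 2 of the identity genes (camera adjusted p = 0.153), 4 and 2 of the CD4 and CD8 lineage (0.0934), 3 and 1 of the neuropilin list (0.326), 4 and 1 of the inhibitory receptors (0.171) and 2 and 5 of the cytokine receptors (0.300). They were 1 and 0 for interferon response (0.685) and MHC class II genes (0.0792), and 1 and 2 for B cell markers (0.284). Fetal genes had 2 lower, heat shock genes 1, monocyte markers 2 and glycolysis genes 2. Cholesterol synthesis genes (camera adjusted p = 0.685 with the block) and mitochondrial transcripts had 0 called by limma with the block, and 1 and 6 at an unadjusted p under 0.05 (0 by limma-voom without it). Interferon response genes had a median just under 0 and a mean of 0.04 units.

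The counts without the block moved when single libraries were left out, from 9 to 50 higher and from 7 to 28 lower genes, with the most without adult CD4− replicate 5. Of 22 called genes that the rule names, 10 kept their call without each library in turn, and CD8A, PECAM1, KLRD1, IL17RE, STYK1, CTSL, RTKN2, ANKRD55, FBLN7, GCSAM and FASLG were among the 12 that did not. These fits had no donor block, so they do not test the differences within donors. With the fixed donor block and all adult libraries, 22 of the 22 kept their call. Within lower-case titles, also without the block, 46 genes were higher and 40 lower, and within capital titles 0 and 1 by limma (197 genes at an unadjusted p under 0.05). All 3 groups shared 1 fit, so cord CD4+ replicate 6 entered the spread within capital titles. Neither kind of fit was repeated with the block.

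Cord CD4+ against adult CD4− cells differs in source and subset together. Cord cells carried more CD4, NRP2 and CSF2RB transcripts, and fewer transcripts of SLC4A10, GZMK, KLRD1, PLEK and TYROBP. In all, 967 genes were higher and 961 lower, 530 and 560 by at least 1 unit. CD4 differed by 7.22 ± 0.41 units, NRP2 by 6.32 ± 0.40, NPTX1 by 5.38, PLS3 by 5.24 and CSF2RB by 5.10. SLC4A10 (9878 to 24.4 counts) differed by −7.14 ± 0.82 units, GZMK by −6.02 ± 0.55, KLRD1 by −5.74, PLEK by −5.62 and TYROBP by −5.29. NRP1 differed by 1.57 units (adjusted p = 0.0307, 5 of 6 cord libraries above every adult CD4− library), IL10 by 3.54 (adjusted p = 1.2e-05, 6 of 6), CD8A by −3.79 (adjusted p = 2.0e-04, 6 of 6 below) and CD8B by −2.29 (adjusted p = 0.0346, 5 of 6 below). The NRP1 call was lost without adult CD4− replicate 1 (adjusted p = 0.0502), 2 (0.0674) or 3 (0.0694) and without cord CD4+ replicate 1 (0.0589), 4 (0.0805) or 5 (0.0790). It was also lost on log2 counts (0.0807), with the 2 groups alone (0.0627), with limma-voom (0.105) and within capital titles (0.540). The CD8B call was lost without adult CD4− replicate 5 (adjusted p = 0.0739) or 6 (0.0900), without cord CD4+ replicate 1 (0.0629), 2 (0.0842), 3 (0.0596) or 5 (0.0878), with the donor as a random block (0.0573), with the 2 groups alone (0.0737) and within capital titles (0.273). Within capital titles CD8A (adjusted p = 0.0601) and IL10 (0.0506) were not called either. Cord CD4+ replicate 6 is among the cord libraries with those titles.

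Among the lists, 12 of 15 cytotoxic effectors fell (camera adjusted p = 4.7e-10; adjusted p = 0.0530 with an estimated correlation). Of 18 NK receptors and adaptors, 12 fell and 2 rose (camera adjusted p = 3.3e-09; adjusted p = 0.0530 with an estimated correlation). Of 17 Th1 genes 8 fell (camera adjusted p = 1.8e-07; adjusted p = 0.0530 with an estimated correlation), and of 7 Th17 genes 5 fell (camera adjusted p = 1.1e-04; adjusted p = 0.120 with an estimated correlation). Of 25 NKT10 and regulatory genes, 11 rose (camera adjusted p = 1.1e-04; adjusted p = 0.120 with an estimated correlation). Cholesterol synthesis (9 of 18 lower; camera adjusted p = 4.3e-09; adjusted p = 0.120 with an estimated correlation) and immediate early genes (9 of 18 lower; camera adjusted p = 1.5e-06; adjusted p = 0.120 with an estimated correlation) were lower. MHC class II genes were lower, with 5 of 10 called (camera adjusted p = 1.5e-05; adjusted p = 0.185 with an estimated correlation). Glycolysis genes were higher, with 9 of 19 called (camera adjusted p = 1.1e-05; adjusted p = 0.226 with an estimated correlation). Fetal genes were higher, with 4 of 5 called (camera adjusted p = 0.00348; adjusted p = 0.185 with an estimated correlation). All 4 tested monocyte markers were higher (camera adjusted p = 2.0e-04), and this list kept its call with an estimated correlation (adjusted p = 0.0290). Only 4 of its 15 listed genes were tested, and VCAN passed the filter only through the cord libraries. The tested members are thus not independent of the cord values. Mitochondrial transcripts were lower with 0 of 13 called by limma (4 at an unadjusted p under 0.05, 0 by limma-voom; camera adjusted p = 0.00322; adjusted p = 0.472 with an estimated correlation), and of 6 MAIT cell markers 3 fell (camera adjusted p = 0.0432; adjusted p = 0.413 with an estimated correlation). The other 12 lists were not called, and the median and mean differed in sign for identity genes (−0.19 and 0.59 units), the CD4 and CD8 lineage (−0.31 and 0.32) and cytokine receptors (−0.18 and 0.48). Adjusted over the list alone, 12 cytotoxic effectors, 9 Th1, 5 Th17, 15 cholesterol synthesis, 11 immediate early, 6 MHC class II and 3 MAIT genes were lower. Adjusted in that way, 13 NK receptors and adaptors were lower and 2 higher, and 11 NKT10 and regulatory, 10 glycolysis, 4 fetal and 4 monocyte genes were higher. Without cord CD4+ replicate 6, 1510 genes were higher and 1644 lower. In lists, that left chemokine receptors and integrins with 3 higher (against 1), cytokine receptors with 4 lower (against 2), cell cycle genes with 3 higher (against 0), and 1 more call each among Th1 (higher), heat shock (lower) and MAIT genes (higher). Within lower-case titles 1612 were higher and 1712 lower, and within capital titles, which include cord CD4+ replicate 6, 108 and 140.

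The cord and the CD4− differences from adult CD4+ cells share their control libraries. Across 12213 genes their correlation was −0.0548, against 0.216 (0.175 to 0.252) in 100 simulations of unchanged groups with shared controls. With donors split so that each contrast had its own adult CD4+ libraries, the mean over 20 splits was −0.0823 (−0.224 to 0.108). The covariance was −0.0127, against 0.00942 in the simulations, a difference of −0.0221. Of the 655 genes lower in cord and the 763 higher in CD4− cells with the donor block, 97 were shared, and of the 657 higher in cord and 583 lower in CD4− cells, 67 were. In the same direction, 46 were shared among higher and 46 among lower genes. Unchanged groups with the shared controls, in lists of the same sizes, shared in that order 19.5 (8 to 28), 14.7 (5 to 30), 89.3 (69 to 112) and 71.8 (53 to 101) genes in 100 simulations, and independent lists would share 40.9, 31.4, 41.0 and 31.3. The simulations leave out the effects and the independent lists leave out the shared controls, so an excess over either is not by itself a shared effect. In the 20 splits of the donors, the calls shared averaged 37.4 (22 to 49), 18.7 (11 to 32), 6.65 (2 to 20) and 11.8 (2 to 46), against 6.69, 4.52, 5.82 and 5.26 for independent lists of their sizes. These values are across genes, which are not independent replicates.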

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

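The position, gene-by-gene and ZBTB16 tests of cord CD4+ replicate 6, the test of separate rounds and the count of abundant monocyte genes were chosen after the results were seen.

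Of 339 groups of 6 tested for a library far from the others, 22 had one. Chance gives about 1 in 20, a share that need not hold for genes near the floor. Cord CD4+ replicate 6 had 6 of them. On the first component it scored −24.3 against 46.0 to 68.3 in the other cord libraries, it had 1464 genes with no read against 681 to 964, and its 50 largest genes took 21.02% of reads against 12.8% to 15.9%. Its values for NCR3 (11.00 against 8.86 to 9.63), EGR1 (13.76 against 9.59 to 10.87) and FDFT1 (12.49 against 11.28 to 11.64) also stood apart.

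Cord CD4+ replicate 6 lay near the adult libraries, and its cause is open. On 660 genes lower in the other cord libraries its median position was 0.105, with 0 at the adult and 1 at the cord mean, within the adult range (highest 0.215), which is what a mislabelled adult library would show. On 619 higher genes it was 0.235, above the highest adult library (0.120). These genes were chosen with the adult libraries included, which holds those libraries near 0, so this position cannot decide. In a test added after the position test, each adult CD4+ library was held out in turn. Genes were taken whose other 5 adult CD4+ libraries all lay more than 1 unit above every one of cord replicates 1 to 5. The sets held 54 to 76 genes. Cord CD4+ replicate 6 fell to the level of those cord libraries or below at 30.2% of the genes, as a mean over the 6 sets. A held-out adult library did so at 3.39% at most, which argues against a plain adult library. Lower depth is also argued against, since at equal reads, on log2(normalized count + 1) values, it still stood apart. It scored 5.32 on the first component (adult −61.7 to −13.4, other cord 75.2 to 88.3, a gap of 0.842 of the cord range). Its ZBTB16 count was 0.242 of the other cord mean (235 against at least 718, adult libraries as low as 153). On 121 genes more than 10 times higher in the other cord than in adult cells, its median ratio was 0.191. The other cord libraries had ratios of 0.777 to 1.09. Cord CD4+ replicate 6 also had 1832 CD8A counts (other cord 85.7 to 761, adult CD4+ at most 902). It had 783 CD8B counts (other cord 4.61 to 152, adult CD4+ at most 79.3). Its CD4 count was the lowest in cord, at 13236 (adult CD4+ 9668 to 18750). These values cannot decide whether T cells other than iNKT cells could have contributed, which the sort on the iNKT receptor should remove. A biological difference between donors was not tested.

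LYZ, CST3, VCAN and FCER1G were higher in cord CD4+ cells, although the sort required CD3. Carried-over monocytes are argued against, since the median count of CD14, S100A9, CD68, CSF1R, SPI1 and TYROBP in cord was 3.11 against 220 for LYZ, CST3 and VCAN. A single round of preparation cannot be told apart, since 4 of these 4 genes had a positive difference under both title spellings, but the labels do not say that the spelling marks rounds, and the genes were chosen for being higher. A difference of the cord cells themselves may remain, as a hypothesis found and tested on the same data.

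The libraries divided by the spelling of their titles. With the donor as a random block 1883 genes differed between spellings, against at most 899 in other splits of the donors, so chance is argued against. Depth is argued against, since 1771 genes differed with all libraries thinned to equal reads. Separate rounds of preparation or sequencing cannot be told apart from differences between donors, since 0 donors had libraries under both spellings. A first test of the read totals alone was replaced by the thinning test, and no biological explanation was tested.

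Other splits of the libraries gave the following. For cord CD4+ against adult CD4+ (1312 genes) chance is argued against but not excluded. A split exchanging cord CD4+ replicate 6 with adult CD4+ replicate 3 gave 1873 genes, which points to a structure of the samples. Of the 100 splits, 2 were as large, the real one included. With the spelling as a covariate and splits within spellings, chance is argued against but not excluded (2266 genes, highest other 2877, 2 of 100 as large). The same holds for cord CD4+ against adult CD4− (1928 genes, 2 of 100 as large). Its highest other split gave 1931, with cord CD4+ replicate 6 and adult CD4− replicate 5 exchanged. For adult CD4− against adult CD4+ chance is argued against with the donor as a block (1346 genes, highest other 0, 1 of 32 as large). It is also argued against without the block (42 genes, highest other 0, 1 of 32 as large). A share of 1 of 32 is the smallest that these splits can give. Among the adult libraries, a split that follows the title spelling gave 4027 genes in a fit that took both libraries of a donor as independent (1883 with the donor as a random block over all libraries), which points to a structure of the samples. In the cord comparisons such a split gave 0 genes by limma (3260 and 3581 at an unadjusted p under 0.05). The blocked count of 1346 compares within donors.

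The other values far from their group were in single libraries. PLS3 in adult CD4− replicate 5 was 4.80 against 3.71 in the others. ADGRL2 in adult CD4+ replicate 4 was 4.11 against 3.71. P2RY1 in adult CD4+ replicate 5 was 5.07 against at most 4.16. PPP2R2B in cord CD4+ replicate 3 was 3.71 against at least 4.06. IL4R in adult CD4+ replicate 1 was 12.54 against at most 11.85. ARID3A in cord CD4+ replicate 4 was 9.96 against at most 9.44. BTLA in adult CD4− replicate 3 was 9.47 against at most 8.81. CD69 in adult CD4+ replicate 1 was 13.76 against at least 14.49. SLC16A3 in adult CD4+ replicate 6 was 10.42 against at most 9.73. INSIG1 in adult CD4− replicate 4 was 11.73 against at least 12.87. MT-CO2 in cord CD4+ replicate 5 was 15.03 against at least 16.08. CRTAM in adult CD4− replicate 5 was 6.31 against at least 7.11. CYSLTR1 in adult CD4− replicate 4 was 6.21 against at most 5.18. FASLG in adult CD4− replicate 5 was 9.28 against at least 10.37. The mitochondrial share of cord CD4+ replicate 5 was 1.87% against at least 3.69%. The median value of adult CD4+ replicate 6 was 8.40 against at least 8.55.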

How the results depend on the processing

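The limma-voom fit, the spelling covariate with a random block and the spelling covariate without cord CD4+ replicate 6 were chosen after seeing the data. No named gene's call and no called list reversed under an alternative. Lists not called changed direction in 26 of 375 pairs of a list and a setting, of which 2 were called under the alternative, both within lower-case titles (the CD4 and CD8 lineage in adult CD4− against adult CD4+, lower, camera adjusted p = 2.8e-12, and identity genes in cord CD4+ against adult CD4−, higher, 3.0e-05). Both lists hold CD4, the sort gene, and their medians had the opposite sign (0.37 and −0.21 units). These calls therefore do not describe most members. The cause was not tested where a count moved, except where fewer libraries or the pairing of donors show it. For cord CD4+ against adult CD4+ (657 higher, 655 lower), quality weights gave 2621 and 2599, the spelling covariate 1155 and 1111 (all 1312 calls shared), lower-case titles 1696 and 1745, capital titles 38 and 58 (1352 genes at an unadjusted p under 0.05), the covariate without cord CD4+ replicate 6 2034 and 1972, and the covariate with a random block 1018 lower. Leaving out each library gave 475 to 1357 higher and 418 (without cord CD4+ replicate 2) to 1449 lower, both highest without cord CD4+ replicate 6. NRP1 missed the threshold on log2 counts, with only the 2 groups, with limma-voom, within capital titles and without adult CD4+ replicate 1 or 3 or cord CD4+ replicate 1, 4 or 5. For adult CD4− against adult CD4+ (25 higher, 17 lower), a fixed donor block gave 763 and 583, a random block 921 and 784, the spelling with a random block 884 and 686, quality weights 111 and 82, the spelling covariate 42 and 29, lower-case titles 46 and 40, capital titles 0 and 1 (197 genes at an unadjusted p under 0.05), and limma-voom 14 and 10 (24 of 24 shared). The log2 counts gave 14 higher (41.2% of the calls, against 59.5%), and the 2 groups alone 14 higher. Leaving out each library gave 9 to 50 higher and 7 to 28 lower, with 50 and 28 without adult CD4− replicate 5, and leaving out any adult CD4+ library or adult CD4− replicates 1 to 4 lowered a count by more than 1.5 times. For cord CD4+ against adult CD4− (967 higher, 961 lower), quality weights gave 2126 and 2242, lower-case titles 1612 and 1712, capital titles 108 and 140, and the covariate without cord CD4+ replicate 6 2061 and 2145. Leaving out each library gave 760 to 1510 higher and 713 to 1644 lower, the highest without cord CD4+ replicate 6. With an estimated correlation, 0 of 11 called lists of the first comparison, 5 of 13 of the second and 1 of 13 of the third kept their call. With fry, 11 of 11, 4 of 13 and 12 of 13 did, and 3, 0 and 5 more were called. Within capital titles 25 of 85, 1 of 22 and 10 of 14 called genes that the rule names kept their call. Cord CD4+ replicate 6 is among the libraries there. The fits within titles and those without single libraries had no donor block. Depth limited what a count of 0 could show for IL10 to 0.0274 CPM in adult CD4+ cells.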

Other observations

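The list of eicosanoid synthesis and sensing genes, and its test, were chosen after some of its members had been seen. Of 26 tested genes of prostaglandin and leukotriene biology, lipid mediators of inflammation, 6 rose and 3 fell in cord against adult CD4+ cells, and the others were not called. PTGS2, the inducible cyclooxygenase, rose from 30.8 to 1098 ± 1852 normalised counts (SD, n = 6) and PTGS1, the constitutive enzyme, from 3.35 (2.20 without adult CD4+ replicate 6) to 67.8. The PTGS2 mean rests on cord CD4+ replicate 5 (4819 counts, the others 107 to 968). Without it the mean was 353 and the difference 2.50 ± 0.52 units (adjusted p = 0.00534), against 3.19 ± 0.69, and within capital titles PTGS2 was not called (adjusted p = 0.149). PLA2G4A, which releases arachidonic acid, rose from 10.0 to 124 counts. The receptors PTGER3 (for prostaglandin E2, 16.9 to 478 counts) and PTGIR (for prostacyclin, 23.6 to 290 counts) rose, as did PTGIS, the prostacyclin synthase (31.3 to 261 counts). Of the leukotriene pathway, ALOX5AP fell from 8719 to 3020 counts and LTA4H from 1740 to 1152, and AKR1C3, a prostaglandin F synthase, fell from 618 to 39.4 (21.9 without cord CD4+ replicate 6, which had 127). The PTGIS call (adjusted p = 0.0475) was lost when any of 4 cord libraries was left out, with limma-voom (adjusted p = 0.0902) and within capital titles (0.665), and that of LTA4H when either of 2 was (up to 0.0727). Within capital titles PTGER3 (adjusted p = 0.0501), PTGS1 (0.166), AKR1C3 (0.107), LTA4H and CYSLTR1 (0.344 each) were not called either. HPGDS (3.07 units) and CYSLTR1 (1.55 units) are named elsewhere in the text and were left out of the test.

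A first run of the test included the members already named. Of 26 tested members not already named, 9 were called (34.6%, against 10.7% of the other genes; odds ratio 4.42, two-sided Fisher's exact p = 0.00106). A candidate explanation is that cord iNKT cells hold a different eicosanoid program, which these data can raise but not settle, since the list was drawn up after members were seen and genes are not independent. The same list tested in libraries of other cord and adult donors would settle it, and no such libraries were analysed here.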
